A study of Mus musculus with 201 samples.

How the data were processed

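The 201 libraries are 4C-seq libraries of cultured mouse cells. Each was assigned to a cell line, a bait and a replicate from its sample title, which gave 67 groups of cell line and bait. The 3 ESC Pou5f1 libraries titled as controls form a group of their own, and the labels do not say what they control for. The labels do not state whether replicates came from separate cultures.

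The 1 file used is the authors' primer list, deposited as a spreadsheet. Per the file headers, it gives for each library the bait gene, the restriction fragment end (HindIII or DpnII), the chromosome and start of the primer, and the primer bases. HindIII is the enzyme of the first digestion in such a 2-enzyme design by common practice, but the order is not given in the sources used here. Per the submitters' processing notes, Bowtie and the genome build mm9 were used. The role of each is not given in the sources used here, nor is the strand of a primer or whether positions count from 0 or 1, so starts are printed as listed. The list was matched to samples by its title column. For 28 rows that title spells Pou5f1 as Pouf51, and the bait cell of the same row spells it Pou5f1. The list names 3 other baits differently from the titles: Hoxa for Hoxa10, Pcdbh19 for Pcdhb19 and Krt13 for Krt131. All 201 libraries have a HindIII-end primer and 192 have a DpnII-end primer, because 9 DpnII lines of Dppa2 were emptied for this work. The 4 Hoxb libraries have no DpnII position, so 188 libraries have both positions.

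The adapter and the NN bases were removed from each primer to leave its locus-specific part, and letters were set to capitals. All bases left were counted as locus-specific, though the first 2 of 3 Pou5f1 primers differ and may not belong to the locus. Primers were called the same when their whole locus-specific parts were equal. HindIII-end primers whose starts lay within 100 bp were counted as 1 viewpoint. A primer was said to carry part of the HindIII site when its 3' end equalled the first 3 or more of the 6 bases of that site. Of the 30 distinct HindIII-end primers, 5 end in all 6 bases, 11 in 4 bases, 2 in 3 bases and 12 in fewer. Distances are differences between listed starts.

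Neighbouring genes were counted in the RefSeq annotation of GRCm38.p6, at the midpoint of the bait gene or, for Hoxb, Hoxc and Hoxd, of the cluster. Krt131 was counted at Krt13, the name in the list. No position was carried between mm9 and GRCm38. The chromosome in the list and in the annotation was the same for 20 of 20 baits. Genes overlapping a window of 500 kb on each side were counted, the bait included. The planned window was centred on the primer. The gene was used in its place because the build named in the processing notes, mm9, differs from GRCm38. Class means were compared with an exact permutation test, two-sided, at a threshold of 0.05, with Benjamini-Hochberg adjustment over 2 tests. The p-value is 2 times the smaller tail. The test was run on simulated data first. It called 5% of 200 simulated sets of 5 baits against 15 with no difference, and 99% of 200 sets with the mean raised by 2.5 SD. The simulated values were normal, while the gene counts ran from 1 to 67. Neither 4 baits against 16 nor smaller shifts were simulated, so how often the test would call these is not known.

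The bait classes, the tests and the rule for named genes were fixed before the data were examined. The rule names every bait gene in the titles, with full values for baits in at least 4 of the 6 lines and for the extremes of each measure. The primers of Hoxb, Hoxc, Hoxd and Zfp42 are given in addition, chosen after their values were seen. The primer bases of Dppa2 and Pcdhb19 are not reported here. The classes rest on general knowledge of the genes, not on a measurement in these cells. Alternatives were other windows, all annotated genes, other sets of baits, another definition of the same primer, the whole primer with its adapter, and merging lettered replicates. Leaving out each bait of the tested class other than Tbx5 was chosen after seeing the data. So were leaving out gene families (symbols starting with Hox, Pcdh, Krt or Prss) and the viewpoint definition. Matching primers to a genome, GC content around baits and the distance to transcription starts were planned and not run, since no mm9 sequence or annotation was used here. Read depth was not compared, since the list gives none, and the precision of the contact profiles is therefore unknown here. Scripts used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.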

Results

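The series used 4C-seq, an assay that reads which restriction fragments of the genome were ligated to 1 chosen bait fragment, in mouse cells. It covers 20 baits in 6 cell lines. The lines were V6.5 embryonic stem cells (ESCs), iPSCs reprogrammed from fibroblasts with retroviral Oct4, Sox2 and Klf4, partially reprogrammed pre-iPSCs made with c-Myc in addition, and embryonic fibroblasts (MEFs). An ESC line lacking Eed, a core subunit of the Polycomb repressive complex that deposits H3K27 methylation, was paired with a wild-type sibling line. The values used here come from the authors' primer list, which names the bait gene of each library and gives its HindIII-end primer with position, and for most libraries its DpnII-end primer with position. The list holds no read count, so sequencing depth is unknown here and contact frequencies were not analysed here. The comparisons below therefore concern which loci were read in which cells, and whether 2 cell states were read from the same fragment.

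The bait panel held pluripotency genes, Polycomb-bound developmental regulators and other loci. The pluripotency group was Pou5f1, which encodes the transcription factor Oct4, together with Dppa2, Dppa3 and Zfp42, genes used as markers of the pluripotent state, and it took 55 libraries. The Polycomb group was the homeobox gene Hoxa10, the Hoxb, Hoxc and Hoxd clusters and Tbx5, a T-box regulator of heart and limb development, with 50 libraries. The other 11 baits took 96 libraries. They were 1700067P10Rik, Krt131 (Krt13 in the list, a keratin gene), Maoa (monoamine oxidase A), Nfia (a nuclear factor I transcription factor), Pcdhb19 (a clustered protocadherin), Prss22 (a serine protease), Ptprg (a receptor tyrosine phosphatase), Rhbdd1 (a rhomboid protease), Stk35 (a kinase), Ugcg (glucosylceramide synthase) and Vegfc (a lymphangiogenic growth factor). Pou5f1 was the most sampled bait with 28 libraries, followed by Hoxa10 with 21, Pcdhb19 with 20 and Tbx5 with 17. The Pou5f1 count includes the 3 libraries titled as controls and lettered ESC replicates such as 3a and 3b. Zfp42, Maoa and Vegfc had 2 libraries each, all in V6.5 ESCs.

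**Figure D1:**
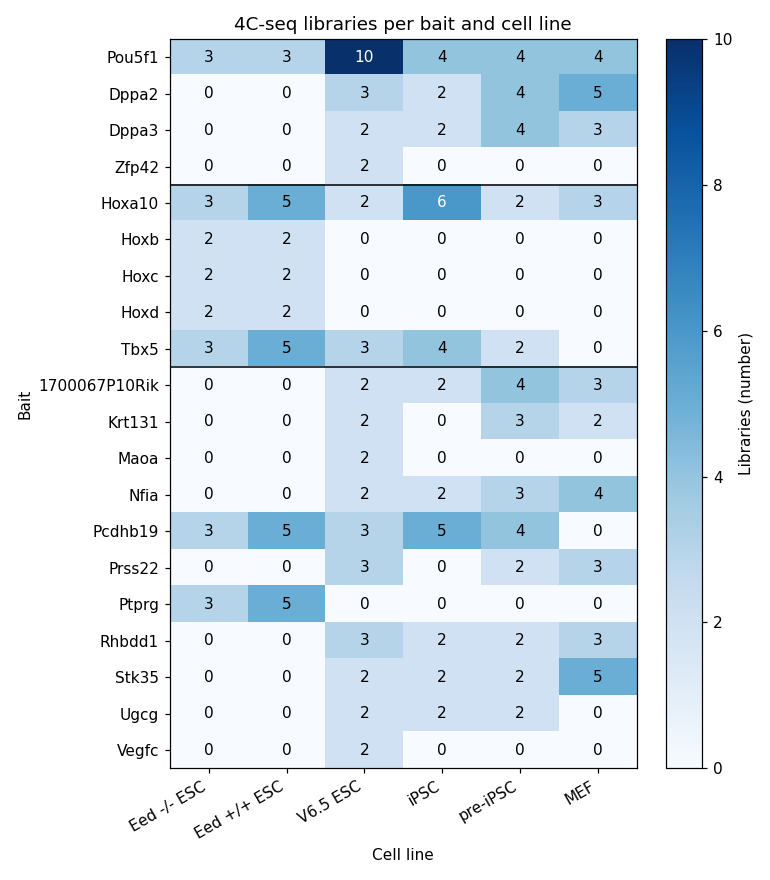
Number of 4C-seq libraries for each bait (rows) in each cell line (columns), with the pluripotency baits on top, the Polycomb baits in the middle and the other baits at the bottom. Pou5f1 and Hoxa10 are the 2 baits with libraries in all 6 lines, and Hoxb, Hoxc, Hoxd and Ptprg have libraries in the Eed lines alone.

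The Eed comparison asks how bait contacts differ when Polycomb repressive complex 2 is lost. Its mutant and wild-type lines shared all 8 of their baits: Pou5f1, Hoxa10, Hoxb, Hoxc, Hoxd, Tbx5, Pcdhb19 and Ptprg. All 5 Polycomb baits were in this set, against 1 of the pluripotency baits. At every one of the 8 baits, both genotypes were read with 1 identical primer pair, so each mutant library had wild-type libraries from the same fragment. The mutant line had 21 libraries, 2 or 3 per bait, and the wild type had 29, from 2 to 5 per bait. Hoxb, Hoxc and Hoxd had 2 libraries in each genotype. With 2 against 2 libraries, a two-sided exact permutation test of a single value cannot reach p under 0.05. Pou5f1, with 3 libraries in each genotype, meets the same limit. Each genotype was a single cell line, so at every bait the libraries repeat that line. An effect of losing Eed therefore cannot be told apart from another difference between the lines.

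The reprogramming comparison sets ESCs against MEFs, pre-iPSCs and iPSCs. V6.5 ESCs had 45 libraries of 16 baits, MEFs 35 of 10 baits, pre-iPSCs 38 of 13 baits and iPSCs 33 of 11 baits. ESCs shared 10 baits with MEFs, 13 with pre-iPSCs and 11 with iPSCs. All 4 of these lines shared 8 baits: Pou5f1, Dppa2, Dppa3, Hoxa10, 1700067P10Rik, Nfia, Rhbdd1 and Stk35. Tbx5 and Pcdhb19 had libraries in ESCs, pre-iPSCs and iPSCs but none in MEFs among those listed. Krt131 and Prss22 had none in iPSCs, and Ugcg had none in MEFs. Pou5f1 and Hoxa10 were the only 2 baits listed in all 6 lines. The limit on an exact test applies here too. Dppa3, Hoxa10, 1700067P10Rik, Krt131, Nfia, Stk35 and Ugcg had 2 ESC libraries each, and the lines set against ESCs had at most 6 libraries of a bait. Such a comparison cannot reach p under 0.05. Baits with 3 ESC libraries can do so only against 5 or more, as Dppa2 has in MEFs and Pcdhb19 in iPSCs. Pou5f1 had 10 ESC libraries, but these include 3 titled as controls and lettered replicates. On its commonest HindIII-end primer it had 3 ESC libraries, against 3 in MEFs, 3 in iPSCs and 2 in pre-iPSCs. There the exact test cannot reach p under 0.05 either.

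The same fragment was not always read in the lines compared. Of the 20 baits, 11 had 1 primer pair throughout, and 9 had more than 1 primer at an end. The 11 were Dppa3, the 5 Polycomb baits, 1700067P10Rik, Krt131, Nfia, Pcdhb19 and Ptprg. The 9 were Pou5f1, Dppa2, Zfp42, Maoa, Prss22, Rhbdd1, Stk35, Ugcg and Vegfc. Another primer need not mean another fragment. The HindIII-end starts lay more than 100 bp apart at Rhbdd1, Stk35, Ugcg and Vegfc alone. They were 2 bp apart at Dppa2 and Prss22, 10 bp apart at Maoa and equal at Zfp42. For Dppa2 the DpnII-end primer was read in 5 of 14 libraries only, since 9 lines of the list were emptied for this work. A single primer pair served both lines at 5 of the 10 baits shared by ESCs and MEFs, at 7 of the 13 shared by ESCs and pre-iPSCs and at 6 of the 11 shared by ESCs and iPSCs. Counting HindIII-end starts within 100 bp as 1 viewpoint, both lines were read from 1 viewpoint at 8 of the 10, 10 of the 13 and 8 of the 11 baits. This count goes by position and does not show which side of a HindIII site was read. Without Pou5f1, whose HindIII-end primers differ within these lines, it was 7, 9 and 7 baits.

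Rhbdd1, Stk35, Ugcg and Vegfc were read from fragments far apart under 1 bait name. ESC replicate 2 of Rhbdd1 had its HindIII-end primer 30152 bp from that of the other 9 libraries. ESC replicate 2 of Stk35 stood 17932 bp from the other 10 libraries, and ESC replicate 2 of Ugcg 33835 bp from the other 5. The 2 ESC libraries of Vegfc were 46796 bp apart. Both primers of each replicate 2 differed in their bases from those of the other libraries of that bait. Counted on the shared fragment, Rhbdd1 had 2 ESC libraries instead of 3, and Stk35 and Ugcg had 1 instead of 2. A comparison of ESCs with another line on that fragment has no ESC replicate for Stk35 or Ugcg. In iPSCs, pre-iPSCs and MEFs, every library of Rhbdd1 and Stk35 used the shared fragment. So did every iPSC and pre-iPSC library of Ugcg, which had none in MEFs. Vegfc had libraries in ESCs alone.

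Pou5f1 was read with 4 HindIII-end primers and a single DpnII-end primer, which starts at position 35641665 of chromosome 17. Positions here and below are those of the list, with strand unstated. The processing notes name the build mm9 but do not say that these positions are on it. The commonest HindIII-end primer, TCCTTAATCTGCTATTGAGGAAGC, starts at 35641076 and served 17 of the 28 libraries. The primers CTCCGCCAAGTTCACAAAGCTT and GACCGCCAAGTTCACAAAGCTT both start at 35641096 and served 6 and 3 libraries. AGCCGCCAAGTTCACAAAG starts at 35641098 and served 2. These last 3 share 17 bases and differ in their first 2, so the count of 4 primers depends on keeping those 2 bases. The commonest primer was used in all 3 libraries of the Eed mutant and all 3 of its wild-type sibling, in 3 of 10 ESC libraries, 3 of 4 iPSC libraries, 2 of 4 pre-iPSC libraries and 3 of 4 MEF libraries. Of the 10 ESC libraries, 3 are titled as controls, and these used the 22-base primers.

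**Figure D2:**
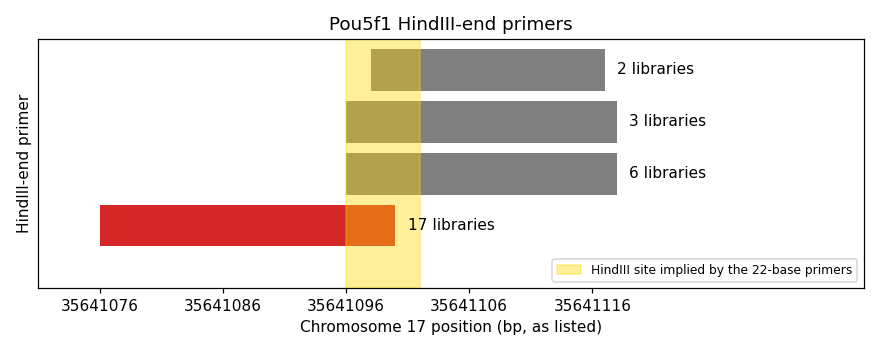
Positions of the 4 Pou5f1 HindIII-end primers on chromosome 17 (x axis, bp as listed), 1 bar per primer drawn from its listed start over its length, with the number of libraries beside it. The primer of 17 libraries (red) starts 20 bp below the pair of 22-base primers, and the shaded band is the HindIII site that the 22-base primers imply if they read the reverse strand.

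At the Polycomb baits every library used 1 primer pair. The Hoxa10 bait, called Hoxa in the list, used CTCATCCGCTCATACCAAGC, starting at 52132916 of chromosome 6, in 21 libraries. Its DpnII-end primer starts 931 bp away at 52131985. The Tbx5 primer CCTTCACCTATAGTTCTCAGACAAA starts at 120305804 of chromosome 5, 358 bp from its partner. The Hoxb primer ATTCTCCAACCCCACTATGC starts at 96193397 of chromosome 11, and its DpnII-end primer has no position in the list. The Hoxc primer CCCCAGCCTACCCAGAAAG starts at 102851549 of chromosome 15, 564 bp from its partner. The Hoxd primer GAGACTGGTGGTCAGCTCTTG starts at 74515299 of chromosome 2, 268 bp from its partner. Among the pluripotency baits, the Dppa3 primer TCTTCATGATTATAAGTTGGAAGCTT starts at 122527612 of chromosome 6, 273 bp from its partner. The Zfp42 primer CCCAGTTATCACACACAGAGTCA starts at 44390650 of chromosome 8, with partners 898 and 899 bp away in its 2 libraries. Dppa2 was read from 48294678 of chromosome 16 in 12 libraries and from 48294676 in 2. Its commonest pair was 623 bp apart, in 3 of the 5 libraries where both positions were read. Of the other baits listed in at least 4 lines, 1700067P10Rik was read with GCCTGGGAGACTTTTCTTTACC from 48233294 of chromosome 17, 565 bp from its partner. The Nfia primer ACAGGCTGTGTAGAGTAAAAGC starts at 97437687 of chromosome 4, 1191 bp from its partner. The shared Rhbdd1 primer AAGCGATGGAGATGCTGAAC starts at 82315774 of chromosome 1, 1407 bp from its partner. The shared Stk35 primer TGCCTCTACTCTAGAAAATGACAGC starts at 129629704 of chromosome 2, 247 bp from its partner. The Pcdhb19 pair stood 1116 bp apart. Whether these positions fall in an exon, an intron or outside the gene was not determined, because no annotation of the build named in the labels (mm9) was used here.

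Across the 29 distinct pairs of positions, the primers of a pair started between 247 and 1553 bp apart, with a median of 638 bp. Both extremes belong to Stk35, the shorter to its shared fragment and the longer to ESC replicate 2. The 30 distinct HindIII-end primers had a locus-specific part of 22.1 ± 2.01 bases (SD, n = 30) with a GC content of 47.5% ± 7.25 (SD, n = 30). The 26 distinct DpnII-end primers had 20.5 ± 1.36 bases and 50.7% ± 7.71 GC (SD, n = 26). The Dppa3 HindIII-end primer had the lowest GC content of its kind at 30.8%, and the Hoxc primer had the highest at 63.2%. Among DpnII-end primers, that of Dppa2 had the lowest at 33.3%, and those of 1700067P10Rik and Hoxb the highest at 66.7%. Mean HindIII-end GC content ran from 44.4% ± 7.24 (SD, n = 12 primers) in iPSCs to 49.4% ± 8.35 (SD, n = 8 primers) in each Eed line. These ranges overlap, and because lines share primers no test was made between them.

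The bait genes lie in surroundings of very different gene content, counted in the GRCm38 annotation. Pou5f1, in the major histocompatibility region, had 62 protein-coding genes within 500 kb on either side of its midpoint, itself included. Dppa3 had 19, Zfp42 had 8 and Dppa2 had 5. Among the Polycomb baits, Hoxc had 27, Hoxb 23, Hoxa10 15, Hoxd 12 and Tbx5 3. Of the other baits, Pcdhb19 had 67, Krt131 (counted at Krt13) 57 and Prss22 48, while Nfia had itself alone. 1700067P10Rik, a long noncoding RNA gene and so not counted itself, had 27. Stk35 had 13, Ugcg 12, Rhbdd1 and Vegfc 7 each, Maoa 5 and Ptprg 4. The 4 pluripotency baits averaged 23.5 ± 26.4 genes (SD, n = 4) against 20.5 ± 20.2 (SD, n = 16) for the rest, a difference of 3 that was within the spread (exact permutation test over 4845 splits, two-sided, p = 0.783, adjusted p = 0.783 over 2 tests). The 5 Polycomb baits averaged 16 ± 9.43 genes (SD, n = 5) against 22.8 ± 23.5 (SD, n = 15), a difference of -6.8 that was also within the spread (exact permutation test over 15504 splits, two-sided, p = 0.569, adjusted p = 0.783). The sign of the first difference rested on Pou5f1, without which it was -9.83 genes, and it was -2 in windows of 250 kb. The sign of the second was 0.6 when all annotated genes were counted.

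**Figure D3:**
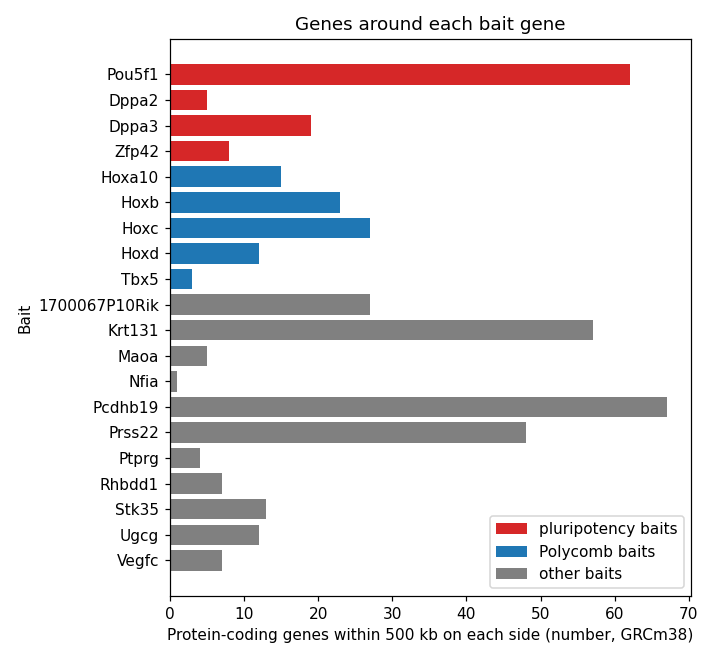
Protein-coding genes within 500 kb on each side of each bait gene or Hox cluster (x axis, number, GRCm38), with pluripotency baits in red, Polycomb baits in blue and other baits in grey. Counts range from 1 at Nfia to 67 at Pcdhb19, and Pou5f1 stands at 62 against 5 to 19 for the other pluripotency baits.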

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

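All tests in this part were chosen after the result was seen. The HindIII-end primer start was compared within the 18 groups that held 4 to 10 libraries, and 3 groups had 1 library apart from the rest by Dixon's test. In each of them the other 3 starts are equal, so any single different start passes, and the result says only that 1 library lists another start. MEF replicate 4 of Pou5f1 started 20 bp from the other 3 libraries, and so did iPSC replicate 2 of Pou5f1. Replicate 3 of Dppa2 in pre-iPSCs started 2 bp from its 3 companions. The Dppa2 primers imply the same HindIII site, at 48294676, when read on the reverse strand.

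The Pou5f1 split runs through the panel: 17 of 28 libraries list the primer at 35641076 and 11 list primers that start at 35641096 or 35641098. That cell line decides which primer was used is argued against, because 4 of the 6 lines (ESCs, iPSCs, pre-iPSCs and MEFs) hold both kinds. The next 3 tests take a listed start as the lowest coordinate of the primer, which the list does not state. That both primers read the same side of 2 neighbouring HindIII sites on the reverse strand is argued against by their bases: where the commonest primer would overlap the other site, 2 of 4 bases match it. That both primers read the same side of 2 neighbouring HindIII sites on the forward strand is argued against by the bases of the site. The sites would start at 35641096 and 35641112. Between the primers, 1 of the 2 bases where they overlap outside the varying first 2 matches, which is too few to decide. But a HindIII site reads AAGCTT, so the first site would read GCTT from 35641098, where both 22-base primers read CCGC. The 19-base primer would place its site at 35641114, 2 bp from that of the 22-base primers with which it shares 17 bases, against 1 bp when these are read in reverse. That the primers face each other across 1 HindIII site goes with the listed positions. The commonest primer, read forward, and the 22-base primers, read in reverse, place the site start 0 bp apart, at 35641096, and the 19-base primer places it at 35641095. If so, the listed positions place the commonest primer below that site, apart from the site bases at its 3' end. It would then lie outside the stretch between the site and the shared DpnII-end primer at 35641665. A wrongly listed position or DpnII-end primer stays open, since no mm9 sequence was searched.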

How the results depend on the processing

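Leaving out each bait of the tested class other than Tbx5, the families and the viewpoint definition were chosen after seeing the data. No bait outside the tested class was left out on its own. The gene difference of the pluripotency baits kept its sign under 7 of 9 alternatives and reversed to -2 in windows of 250 kb; leaving out 1 bait gave -9.83 (without Pou5f1) to 9.17 genes (without Dppa2). The difference of the Polycomb baits kept its sign under 8 of 9, but shrank to -0.0667 in windows of 250 kb and reversed to 0.6 with all annotated genes; leaving out 1 bait gave -9.55 (without Hoxc) to -3.55 (without Tbx5). No alternative of either passed the threshold (exact permutation p from 0.236 to 0.867 and from 0.297 to 0.953), and the cause of the reversals was not tested. With Hox, Pcdh, Krt and Prss genes left out, the differences were 11.3 and -8.33. None of these genes lay around a pluripotency bait, so 11.3 reflects genes removed around the comparison baits alone. Gene families around the pluripotency baits, such as 5 Clec genes around Dppa3, stayed in. Baits with more than 1 primer numbered 9 by the whole sequence and by the last 15 bases. The 2 primers of Dppa2 and of Prss22 stop at different bases of 1 HindIII site, so comparing last bases could not merge them. The number was 4 when the HindIII end alone was compared and starts within 100 bp counted as the same. The 8 baits shared by ESCs, iPSCs, pre-iPSCs and MEFs stayed 8 in number with control-titled libraries left out and lettered replicates merged (194 libraries). This number could not change, since merging removes no bait from a line and other ESC Pou5f1 libraries remain. Mean HindIII-end GC content was 49.2% over whole primers, with the NN bases counted in the length but not as G or C. No paired analysis was possible because the list gives no measured value per library and the tests compare bait loci. Other settings for primer matches to a genome, distance to transcription starts, GC content around baits and read depth were not run. Depth limits no value here, since none is a read count.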

Other observations

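The neighbours named in this paragraph, from GRCm38, were chosen after seeing the data. Dppa3 lies between Gdf3 and Nanog, the latter a core pluripotency transcription factor, as the nearest protein-coding genes on either side. Dppa2 lies between its relative Dppa4 and Morc1, a gene of the male germ line. Zfp42 has Triml2 and Adam26b as its nearest neighbours. Tbx5 lies beside Tbx3, another T-box regulator, with Rbm19 on the other side, and these 3 are all the protein-coding genes in its window. The Hoxd cluster is flanked by Evx2, a homeobox gene, and Evx1 lies in the window of Hoxa10. Hox genes made up 11 of the 15 coding genes around Hoxa10, 10 of 23 around Hoxb, 9 of 27 around Hoxc and 9 of 12 around Hoxd. Protocadherins made up 57 of the 67 around Pcdhb19, and keratin or keratin-associated genes 30 of the 57 around Krt13.

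The odd Rhbdd1, Stk35 and Ugcg viewpoints in ESCs were tested after they were seen. Under a typing error in 1 position, the primer bases would be the usual ones, but 3 of the 3 baits have other bases at both ends, which argues against it. The libraries are all replicate 2 of V6.5 ESCs, as is the second Vegfc library. No biological explanation was tested.

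The 3 Pou5f1 primers that start at 35641096 or 35641098 share 17 bases. They differ in the first 2 bases left after the adapter was removed, with a different pair of bases in each. The 22-base primers have the same listed start and length, so their pairs cannot both match 1 reference sequence there. Whether any pair belongs to the locus was not determined, and all were kept in primer counts, lengths and GC content. ESC replicates 5a and 5b of Pou5f1 carry different primers of these 3, as do the control-titled libraries 1 and 2.

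A guess about the Polycomb baits, tested on these data, met no clear excess to explain. It held that these baits lie among more protein-coding genes than the others because their own gene clusters are counted. They averaged fewer, by a difference of -6.8 that was within the spread, so no excess of coding genes was there to explain. The difference was -0.0667 in windows of 250 kb and 0.6 with all annotated genes, so its direction is not settled. With Hox, Pcdh, Krt and Prss genes left out, the Polycomb baits averaged 8.2 ± 6.91 genes (SD, n = 5) against 16.5 ± 16.7 (SD, n = 15), a difference of -8.33 (exact permutation test, two-sided, p = 0.297, chosen after seeing the data).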
